A study of Mus musculus with 2 samples.

How the data were processed

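ATAC-seq libraries of hindbrain tissue from mouse embryos at embryonic day 14.5 were analysed, 2 biological replicates of 1 group per the labels, with fragments of 200 to 750 bp. Replicate 1 pooled 17 embryos and replicate 2 pooled 34. The replicate numbers come from the labels and pair nothing, since there is only 1 group. The replicates are separate pools of animals, so the spread between them holds both biological and technical variation. The analysis started from 12 peak lists that the authors deposited on mm10. The peak caller, the aligner and their versions are not given in the sources used here, and the reads were not analysed here, so read depth is unknown and no value rests on counts.

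Per the metadata deposited with the files, the authors made peak lists for each replicate and for both together: lists thresholded on the irreproducible discovery rate (IDR), a conservative thresholded list, a replicated list, pseudoreplicated lists, and lists ranked by IDR. The thresholded, replicated and pseudoreplicated lists hold no entry on unplaced or unlocalized contigs, and were made with 1 further parent file whose content is not stated. Each entry carries a fold enrichment over background, a ratio that the authors deposited for each entry and that is comparable within a list. The deposited −log10 p and −log10 q columns are the authors' own per-entry statistics. The deposited score is a scaled IDR in the thresholded and ranked lists, capped at 1000 and starting at 540 in the thresholded ones, and 10 times −log10 p, capped, in the replicated and pseudoreplicated lists. The deposited summit offset counts base pairs from an entry's start. Several entries share 1 region, up to 11, so the summit was the unit of analysis and regions are given beside it. No entry was identical between the replicates' thresholded lists, which were checked for a library deposited more than once.

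Genes and transcription starts came from the GENCODE basic annotation of GRCm38, release M21, and sequence from the GRCm38 assembly, which mm10 names. There were 21827 protein-coding genes with 41438 starts, and 77161 starts over all annotated genes. A summit within 1 kb of any annotated start was called promoter, and others were called exon, intron or intergenic in that order. For gene lists, motifs and the strongest peaks, promoter meant within 1 kb of a protein-coding start, and every other summit was distal and was assigned to the nearest protein-coding start. By that definition 27656 summits of the series list were distal, against 24974 with every annotated start. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and samtools 1.23.1, and sequence matching used blastn 2.17.0.

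The main list was the series' thresholded list. Overlap between replicates meant at least 1 shared base pair of a region, and it was tested against 1000 random placements of the regions on their own chromosome, one-sided. The share of promoter summits was tested against 1000 placements, two-sided. Recovery of promoter and distal peaks was compared with Fisher's exact test over peaks, two-sided. For 33 gene lists, the share with a promoter peak and the number of distal summits per gene were each set against 10000 random lists of the same size, two-sided, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Random lists were matched in 10 classes, on the CpG observed over expected ratio within 1000 bp at the start for promoters, and on the length of the stretch nearest to the gene for distal summits. Hox paralogs 1 to 5 and 9 to 13 were compared with Fisher's exact test over genes, two-sided.

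For 30 consensus motifs, the share of summits with a match within 75 bp on either strand was divided by the mean share in windows of the same 151 bp centred 1 kb to either side. An exact sign test over discordant summits, with 1 flank drawn at random per summit, was adjusted by Benjamini-Hochberg over all 60 tests. A motif was called enriched at an adjusted p under 0.05 and a ratio of at least 1.2. HNF1 sites were too rare for a ratio.

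Gene lists, motifs, tests, thresholds and other settings to try were fixed before the data were examined. So was the rule for genes the text names: in each list the 3 members with the most distal summits and up to 3 without a promoter peak in alphabetical order, the 10 genes with the most distal summits, the genes nearest the 10 strongest promoter and the 10 strongest distal summits, and every Hox gene. Other names are said to be chosen after their values were seen. An older symbol in a list was matched through its current name, so Drgx entered as Prrxl1.

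The list tests were checked on simulated lists of the 21827 genes. With 20 lists lowered to a 20% chance of a promoter peak, 12 were called, with 20 raised to a 95% chance, 17, and 0 of 20 unchanged lists were called in each case. With 20 lists raised 4-fold in distal summits, 14 were called, and 1 of 20 unchanged lists. In simulated peaks of which 49.8% were kept in a partner list, the overlap found 50.2%. Motifs planted in 5% of 5999 shuffled windows were called for 29 of 30 motifs, the CAGMTG E-box being missed, and 0 were called without planting. The background there was other shuffles of the same windows, not flanks. That check therefore gives no rate of false calls against flanks, which can differ in base composition.

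The other settings were other overlap rules (50% of each region, or summits within 150 bp), equal list length, the pseudoreplicated, replicated and conservative lists, only summits of at least the median enrichment, promoter distances of 500 bp and 2.5 kb, protein-coding starts only, unmatched random lists, assignment to every gene within 50 kb, shuffled windows as motif background, 50 bp motif windows, −log10 p in place of enrichment, and each replicate left out in turn. Added after seeing the data were 1 summit per region, only summits with a −log10 q of at least 2, and the paired −log10 p of the list ranked over both replicates. Alternatives used 100 placements each. Under an alternative, a gene list or motif called in neither setting was counted as the same whatever its direction.

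Matches to the mitochondrial genome and to other nuclear places required 90% identity over at least 50% of a region. The cover was first set lower and was changed to 50 before that test was run, after a looser exploration had shown such matches among strong regions, so these tests followed a look at the data. The ranked lists were used only for the paired alternative and for values of the closing section, and signal tracks were not used here.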

Results

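The data describe open chromatin in the hindbrain of mouse embryos at embryonic day 14.5, measured with ATAC-seq, in which the Tn5 transposase cuts and tags accessible DNA. All libraries form 1 group of 2 biological replicates. Replicate 1 pooled the hindbrains of 17 embryos and replicate 2 those of 34, of both sexes and of strain B6NTac;B6NCrl/Lap. The authors deposited peak lists on mm10, in which each entry is a peak summit with its fold enrichment over background. The thresholded list made from both replicates together, called the series list here, holds 62298 summits in 24325 regions that cover 23.4 Mb. It includes peaks found in neither replicate's own list. A stricter conservative list, with 54912 summits, contains 99.5% of the entries that passed when both replicates were ranked side by side. Replicate 1 alone has 31983 summits in 12964 regions, and replicate 2 alone has 54439 in 21390. Read depth is unknown, so the lists give presence and rank of peaks but not counts. Every share and p below describes these 2 libraries.

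The first question was where in the genome hindbrain chromatin was open. In the series list, 59.9% of summits lay within 1 kb of an annotated transcription start, 19.4% in introns, 18.4% between genes and 2.34% in exons. Regions can hold several summits, and with 1 summit per region the promoter share was 52.3%. In longer lists the promoter share was lower, 39.0% in the replicated list and 36.4% in the pseudoreplicated list. Randomly placed peaks reached promoters in 4.51% of cases (permutation p = 0.002, two-sided, the smallest that 1000 placements can give). Of 21827 protein-coding genes, 12255 (56.1%) had a promoter peak, with 50.6% ± 4.99 (SD, n = 2) over the replicate lists. CpG content divided the genes: over 10 classes of the promoter CpG ratio, the share with a peak rose from 0.596% in the lowest to 96.1% in the highest. The 10 strongest promoter peaks, at 22.4 to 24.5 fold enrichment, lay within 0.086 kb of their start. They belonged to Iars and Tars, which encode aminoacyl-tRNA synthetases, the helicase gene Hltf, Tmem218, Cfdp1, Fggy, Depdc1a, Fopnl, 6720489N17Rik and 2610008E11Rik. The promoter share was 82.6% in replicate 1 and 63.7% in replicate 2, or 73.1% ± 13.4 (SD, n = 2).

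**Figure D1:**
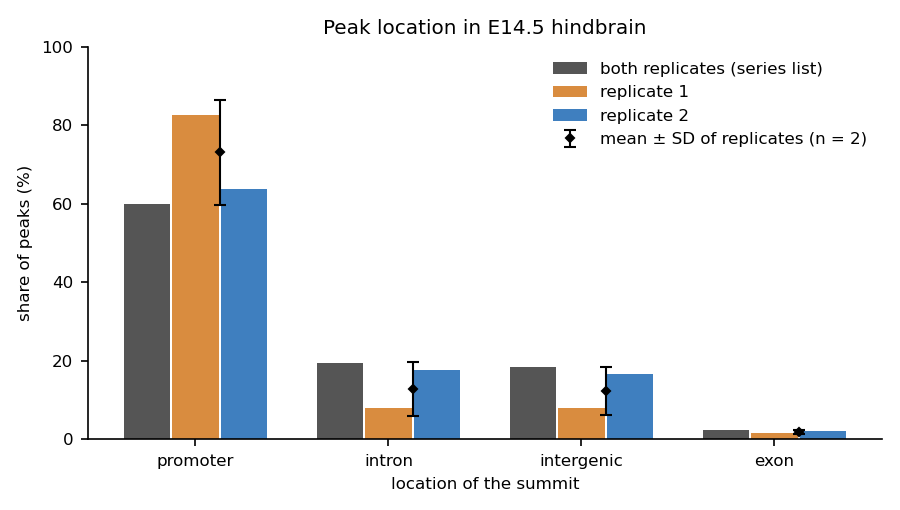
Share of peak summits (percent) at promoters, in introns, between genes and in exons. Bars show the series list and each replicate, and the diamond shows the mean ± SD of the replicates (n = 2), which at promoters is 73.1 ± 13.4.

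The next question was which groups of genes had open promoters in hindbrain. Members of the pan-neuronal, progenitor, housekeeping and cell cycle lists mostly did. None of these lists was called higher than lists matched on CpG ratio, which averaged 74.1%, 82.4%, 86.8% and 88.9% in that order. A peak marked the promoters of 16 of 17 pan-neuronal genes, such as Myt1l, a neuronal transcription factor, and Gap43, a growth cone protein; Rbfox3, a marker of mature neurons, had none. It marked 20 of 23 neural progenitor genes, including Sox2 and Sox9, against 10 of 23 in the list of replicate 1, all 21 housekeeping genes and 19 of 20 cell cycle genes, where Aurkb had none. Lists of other brain regions and other tissues had lower shares, as had some lists of neuron classes found in the hindbrain. Several of these were not called lower than lists matched on CpG ratio, as given below. The forebrain list had a peak at 5 of 22 members, and Foxg1, a regulator of telencephalon growth, Dlx1, Dlx2, Dlx5 and Tbr1 were among those without. The 5 with a peak were Arx, Bcl11b, Dlx6, Neurod6 and Satb2.

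Each of 33 gene lists was set against 10000 random lists of protein-coding genes matched on promoter CpG ratio. Fewer members than in matched lists had a promoter peak in 14 lists, with adjusted permutation p from 0.00132 to 0.0306 (two-sided, Benjamini-Hochberg over the lists). None of the 8 genes of Hox paralogs 6 to 8 had one, where matched lists averaged 87.4%, and none of the 16 genes of paralogs 9 to 13, where they averaged 82.9%. The forebrain share was 22.7% (matched 78.6%; 15.9% ± 3.21 over replicates, SD, n = 2). The germ cell and testis list had a peak at 3 of 15 members (Dazl, Tex14 and Zpbp) and the epidermis and epithelium list at 1 of 14 (Krt10), against 60.4% and 48.8% in matched lists. Endothelial genes had 4 of 16 (Cldn5, Ets1, Kdr and Mfsd2a), and Cdh5, which encodes the endothelial cadherin, and Emcn had none. The midbrain list had 4 of 9 (Nr4a2, Otx1, Pitx2 and Tal2), and Otx2, which patterns forebrain and midbrain, had none. In the longer replicated list all midbrain members (100%) had a peak, which reversed the direction. Replicates 1 and 2 alone had 3 and 4 of the forebrain, 1 and 3 of the endothelial, 2 and 3 of the midbrain and 0 and 1 of the epidermis genes. Of the receptor lists, 2 of 1091 olfactory receptor genes (Olfr658 and Olfr94, with 0 in replicate 1) had a peak, 0.183% against 3.96% in matched lists. A peak marked 1 of 326 vomeronasal receptor genes (Vmn1r4), 0.307% against 1.85% in matched lists.

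Lists of neuron classes found in the hindbrain were also among these 14. Excitatory neuron genes had a promoter peak at 5 of 13 members (Atoh1, Lmx1b, Pou4f1, Slc17a6 and Tlx3; matched 79.9%), serotonergic genes at 6 of 15 (matched 69.8%) and noradrenergic genes at 2 of 8 (Ascl1 and Tlx3; matched 64.6%). Cranial motor neuron genes had 5 of 13 (Isl1, Isl2, Nkx6-1, Ret and Tbx20; matched 77.0%), and the neural crest and peripheral nerve list had 5 of 13 (Isl1, Mpz, Ngfr, Pou4f1 and Tfap2a; matched 70.9%). The lists of replicates 1 and 2 held fewer: 1 and 2 of the excitatory, 2 and 3 of the serotonergic, 1 and 0 of the noradrenergic and 3 and 4 of the cranial motor neuron genes. Among the members without a peak were Dbh, the enzyme that makes noradrenaline, Chat, which makes acetylcholine, and Ddc, which makes serotonin and dopamine. Members named because their count was 5 or fewer, here and below, were picked out after their values were seen. The calls for excitatory, serotonergic, noradrenergic, cranial motor, midbrain and neural crest genes rested on the CpG matching: none was past the threshold against unmatched lists, where adjusted permutation p ran from 0.234 to 0.737. In the longer replicated list 7 of the 14 calls were lost, those for serotonergic, noradrenergic, cranial motor, midbrain, neural crest, endothelial and epidermis genes. In the looser pseudoreplicated list these and the forebrain and excitatory calls were lost (adjusted permutation p from 0.136 to 1.0). Neural crest genes were not called without replicate 2, and vomeronasal receptors were not called in either replicate alone.

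No list had promoter peaks more often than matched lists by this permutation test, in which 1 list passed an unadjusted 0.05: pan-neuronal genes, with 94.1% against 74.1% (adjusted permutation p = 0.0625; 91.2% ± 4.16 over replicates, SD, n = 2). Against unmatched lists, 4 lists were called higher and 14 lower. The remaining lists not called had a peak at 13 of 21 rhombic lip and granule cell genes, 13 of 17 Ptf1a and Purkinje cell genes, 7 of 12 isthmus and anterior hindbrain genes (Lmx1b and Pax8 among them, but not Fgf8, the signal of the isthmus) and 9 of 13 inhibitory neuron genes. They also included 11 of 14 astroglial, 5 of 14 oligodendrocyte (Mbp, Myt1, Olig1, Olig2 and Pdgfra) and 6 of 13 choroid plexus and roof plate genes. For cells of the blood and other organs the counts were 5 of 15 mesenchyme, pericyte and meninges genes (Foxc1, Foxd1, Kcnj8, Tbx18 and Twist1), 1 of 16 microglia genes (Irf8), 3 of 16 erythroid genes (Gypa, Klf1 and Tal1), 0 of 15 lymphocyte genes, 1 of 17 hepatocyte genes (Foxa3), 2 of 15 skeletal muscle genes (Actn3 and Mylpf) and 2 of 13 cardiac genes (Myl4 and Nppa). Matched lists averaged 13.1% for lymphocyte, 14.8% for hepatocyte, 15.3% for microglia, 30.9% for skeletal muscle, 30.9% for cardiac and 50.6% for mesenchyme genes. The erythroid share, 18.75%, was above its matched mean, and the others were below theirs. None was called, so these low counts are not shown to differ from those of genes of like CpG ratio. Counts were lower in 1 or both of the lists of replicates 1 and 2, at 1 and 3 isthmus genes, with Lmx1b and Pax8 in neither, 8 and 11 Ptf1a and Purkinje cell, 4 and 6 inhibitory, 6 and 10 astroglial, 2 and 5 oligodendrocyte, 3 and 5 choroid plexus, 0 and 4 mesenchyme, 0 and 1 microglia, 1 and 0 erythroid and 1 and 1 cardiac genes. On simulated lists the test found 12 of 20 lowered to a 20% chance of a peak and 17 of 20 raised to 95%. Those lists were drawn from all protein-coding genes, of which 56.1% had a promoter peak. Matched lists averaged 74.1% for pan-neuronal and 86.8% for housekeeping genes, which left less room for a higher share. A share of 100% of the housekeeping genes was not called (adjusted permutation p = 0.164). The 17 of 20 thus gives no rate for such lists.

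**Figure D2:**
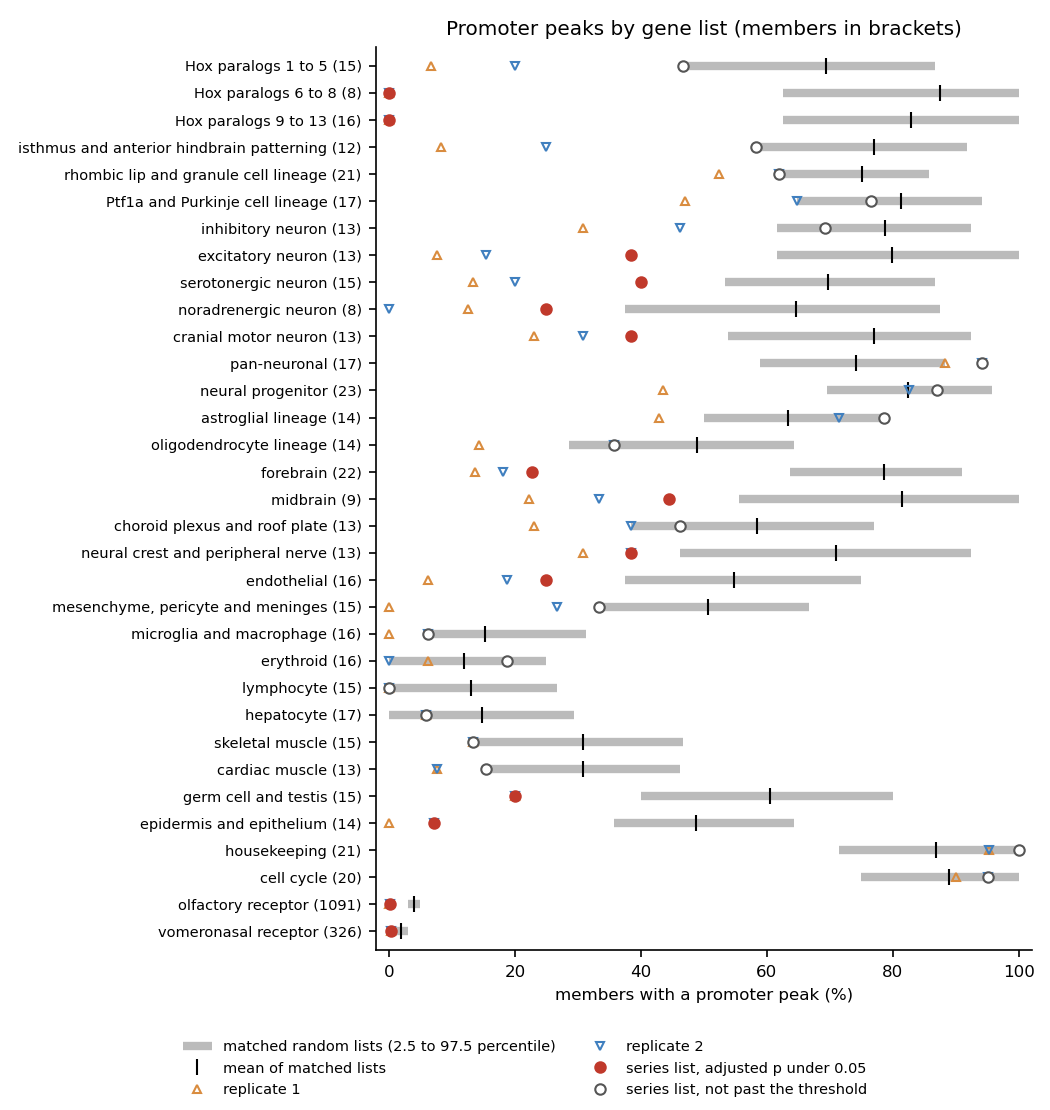
Share of each gene list's members with a promoter peak (percent) in the series list (circles, filled red past the adjusted threshold) and in each replicate (triangles). Grey bars span 10000 matched random lists less 2.5% in each tail, with their mean as a tick, and the Hox 6 to 8, Hox 9 to 13 and forebrain lists lie to the left of theirs.

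Hindbrain segments are patterned by Hox genes at the 3' ends of the clusters, while the 5' genes pattern the trunk, so the 2 ends were compared. Open promoters lay at the 3' end: 7 of 15 genes of paralogs 1 to 5 had a promoter peak, namely Hoxa1, Hoxa2, Hoxa4, Hoxa5, Hoxb4, Hoxb5 and Hoxd4, against 0 of 16 genes of paralogs 9 to 13 (Fisher's exact test, two-sided, p = 0.00245). The strongest was at Hoxa1, with 7.39 fold enrichment at chromosome 6, 52158411. Hoxa3, Hoxb1, Hoxb2, Hoxb3, Hoxc4, Hoxc5, Hoxd1 and Hoxd3 had none in the series list. Nor did Hoxa6, Hoxa7, Hoxb6, Hoxb7, Hoxb8, Hoxc6, Hoxc8 and Hoxd8, or any of Hoxa9, Hoxa10, Hoxa11, Hoxa13, Hoxb9, Hoxb13, Hoxc9, Hoxc10, Hoxc11, Hoxc12, Hoxc13, Hoxd9, Hoxd10, Hoxd11, Hoxd12 and Hoxd13. Of paralogs 1 to 5 without a peak here, Hoxc4 and Hoxd1 had a promoter peak in the conservative list. The looser pseudoreplicated list held these and also Hoxb2, Hoxb3 and Hoxc5. Over the cluster stretches of paralogs 1 to 5, which span 199.6 kb, lay 28 summits (9 in replicate 1 and 15 in replicate 2), against 0 over the 216.0 kb of paralogs 9 to 13. Hoxa5, Hoxb4, Hoxb5 and Hoxd4 had a peak in neither replicate's own list. Replicate 1 alone had a promoter peak at 1 of the 15 genes (Hoxa1) and replicate 2 at 3, which ended the call (Fisher's exact p = 0.484 and 0.101), as did keeping only summits of at least median enrichment (3 of 15). Genes of a cluster are neighbours and not independent, and the list of paralogs 1 to 5 itself did not pass the matched test (46.7% against 69.4%, adjusted permutation p = 0.112).

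**Figure D3:**
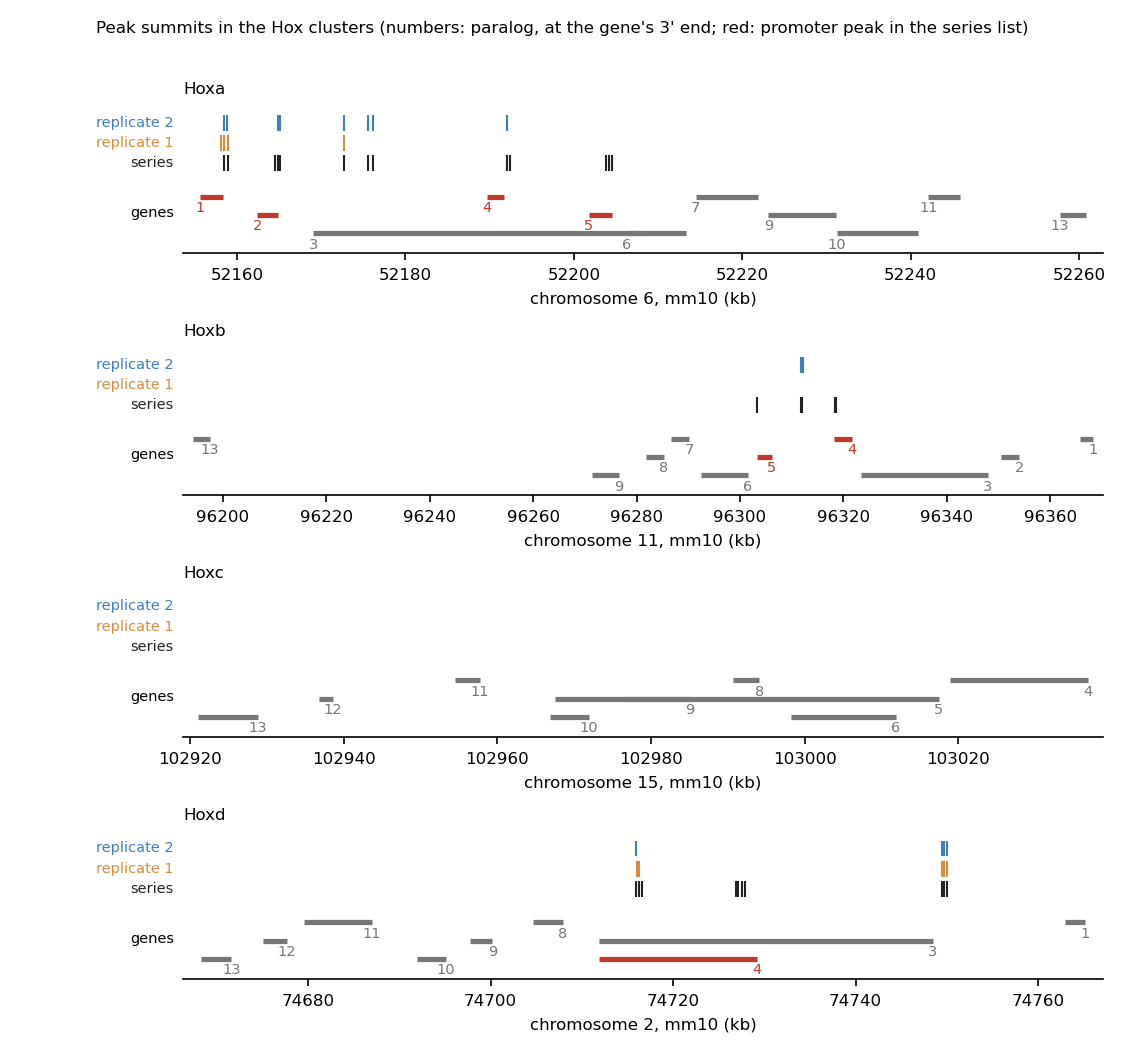
Peak summits of the series list and of each replicate along the Hoxa, Hoxb, Hoxc and Hoxd clusters (mm10, kb), with genes below as bars and their paralog number at the 3' end. Genes in red have a promoter peak, 7 of 15 among paralogs 1 to 5 and 0 of 16 among paralogs 9 to 13.

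Peaks away from promoters were then assigned to the nearest protein-coding start, to ask which genes were surrounded by open chromatin. The astroglial, pan-neuronal and neural progenitor lists were called higher. Astroglial genes had 9.71 distal summits per gene against 2.72 in random lists matched on the stretch assigned to a gene, led by Sox9 (29), Nfib (26) and Nfia (22), transcription factors of glial differentiation. Pan-neuronal genes had 9.18 against 3.28, led by the neuronal transcription factor Myt1l (45), Celf4 (26), which encodes a neuronal RNA-binding protein, and Gap43 (24), though the median gene of the list had 3. Neural progenitor genes had 7.17 against 2.54, led by Sox9 (29), Sox2 (27) and the Hedgehog effector Gli2 (14). The median was 5 per progenitor gene and 7 per astroglial gene. All 3 had an adjusted permutation p of 0.00132, from the smallest p that 10000 lists can give, 0.0002. Olfactory receptors (0.117 against 0.395) and vomeronasal receptors (0.138 against 0.974) had fewer, at the same adjusted permutation p.

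Over the replicate lists the values were 5.07 ± 3.74 per astroglial gene, 4.97 ± 2.70 per pan-neuronal gene and 3.09 ± 2.95 per progenitor gene (SD, n = 2), higher in replicate 2, whose list is longer. Without replicate 2, at 1.00 per gene, the progenitor call was lost. Among the 28 lists not called were rhombic lip and granule cell genes, with 5.43 against 3.07 (adjusted permutation p = 0.163), led by Meis1 (22), Lmx1a (14), a roof plate regulator, and Meis2 (13), and isthmus genes, with 3.92 against 2.08 (adjusted permutation p = 0.256), led by Pax5 (13), Lmx1b (10) and Pax8 (9). Hox paralogs 1 to 5 had 1.13 against 0.366 (adjusted permutation p = 0.163), most of them at Hoxc4 (8) and Hoxd3 (6). Forebrain genes had 2.86 against 2.79, led by Lhx8 (11), Foxg1 (9) and Tbr1 (7), none of which had a promoter peak.

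Over all protein-coding genes, those with the most distal summits were Rapgef5 (49), a Rap guanine nucleotide exchange factor, Myt1l (45), Ubash3b (40), the Notch coactivator Maml3 (39), Auts2 (37), Gm11146 (35), Tmem161b (35), Mef2c (34), a transcription factor of neuronal differentiation, Sfi1 (34) and Zfp608 (33). This order was not the same in each replicate: replicates 1 and 2 had 15 and 34 summits at Rapgef5, 16 and 29 at Myt1l, 11 and 36 at Ubash3b, 21 and 32 at Maml3, 10 and 33 at Auts2, 16 and 34 at Gm11146, 20 and 34 at Tmem161b, 22 and 24 at Mef2c, 19 and 22 at Sfi1 and 11 and 32 at Zfp608. Among these 10 genes the mean was highest at Tmem161b (27.0 ± 9.90, SD, n = 2), and Mef2c had the most regions, 19 against 15 at Rapgef5. Of the 17 regions assigned to Sfi1, 16 matched at least 1 other place in the nuclear assembly, against 1 of 15 at Rapgef5 and 0 at the other 8 genes. Nearest-start assignment can span long stretches: the strongest distal peak assigned to Celf4 lay 999.6 kb from its start.

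**Figure D4:**
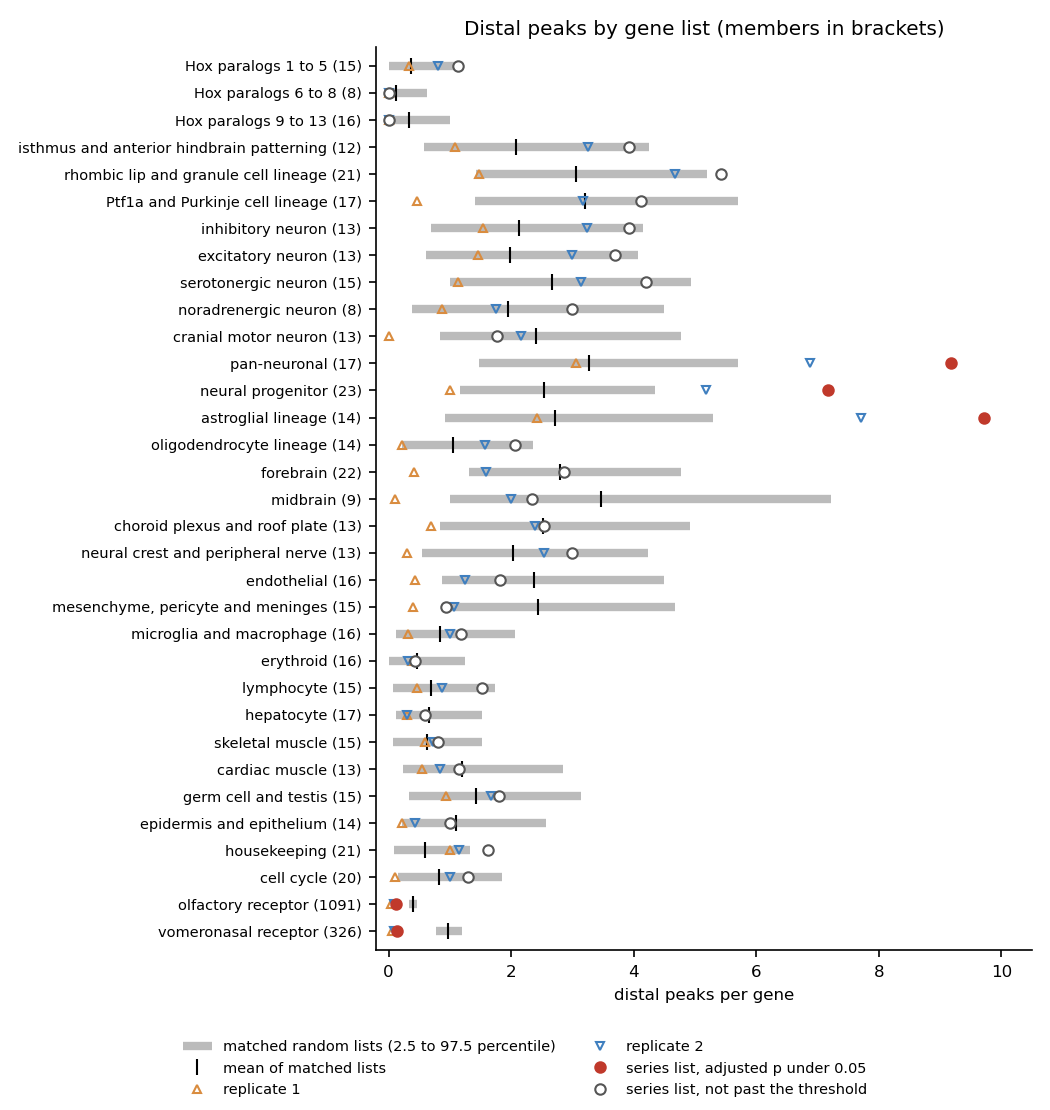
Distal summits per gene for each gene list in the series list (circles, filled red past the adjusted threshold) and in each replicate (triangles). Grey bars span 10000 random lists matched on assigned length less 2.5% in each tail, and pan-neuronal, neural progenitor and astroglial genes lie to the right of theirs at 9.18, 7.17 and 9.71.

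The strongest distal summits stood apart from the rest, with 25.6 to 55.4 fold enrichment where the series list had a median of 4.20. They lay in 9 regions, and the nearest genes were Pak3, Abcb11, G6pd2, Gm5426, Frmd4a, Tyrp1, Galc (for 2 summits), Cldn34d and Myl12b. The first lay 35.5 kb from Pak3, at chromosome X, 143482935 to 143483180. At least 50% of the length of 4 of these regions, those nearest G6pd2, Gm5426, Tyrp1 and Galc, matched the mitochondrial genome at 90% identity or more, against 7 of the 13295 other distal regions (Fisher's exact p = 3.18e-11, two-sided). These 4 were picked out after their values were seen.

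Consensus sites of 30 transcription factor motifs were counted within 75 bp of each summit and in windows 1 kb to either side, to ask which factors' sites mark open chromatin. Distal here means over 1 kb from any protein-coding start, so starts of other genes are included. At distal summits, sites of the insulator protein CTCF were 20.8 times as frequent as in the flanks (3.32% of summits against 0.159%; ratio 18.5 ± 5.10 over replicates, SD, n = 2). RFX sites, bound by regulators of cilium genes, were 19 times as frequent (0.619% against 0.0326%, with a ratio of 44.1 ± 33.8 over replicates). NFI sites, bound by the glial factors Nfia and Nfib, were 8.48 times as frequent (0.644% against 0.0760%, with 10.4 ± 0.934 over replicates). Other settings gave ratios of 2.62 to 20.5 for NFI and 14.9 to 46.7 for CTCF. E-boxes of the CAGMTG type, bound by proneural bHLH factors, marked 26.9% of distal summits against 17.6% of flanks (1.53 times; 1.45 ± 0.0792). POU octamers (1.81), ZIC sites (2.01), MEIS sites (1.56) and EBF sites (1.45) were also enriched, as were NRF1 (5.50), CREB (4.20), SP/KLF (2.95), YY1 (2.71), ETS (1.91), CACGTG E-boxes (1.88) and NFY (1.36). These 15 passed an exact sign test, with adjusted p (60 tests) from 3.31e-212 at CTCF to 0.00334 at EBF, whose call was lost in 4 of 9 other settings, without replicate 2 (ratio 1.04) among them. Distal summits lay in 13304 regions, and near summits can share a site. They are thus not independent, and nor are promoter summits. With 1 summit per region 15 distal motifs were called too, without EBF. TATA box (0.338), HNF4 (0.522), GATA (0.609), ROR (0.647), TCF/LEF (0.709) and OLIG-type E-box (0.736) sites were less frequent than in flanks, and the remaining 9, homeodomain TAATTA (0.995) among them, were not called. Of these, SOX (1.17) and HOX-PBX (0.836) passed the exact sign test on p but their ratios were too near 1 for a call. Against shuffled summit windows in place of flanks the TATA box and OLIG-type ratios turned to 2.09 and 1.06, and the HNF4 difference was not called without replicate 2.

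At promoter summits, 11 motifs were enriched: NRF1 (16.3), a regulator of mitochondrial genes, CREB (9.61), YY1 (9.36), SP/KLF (6.16), ETS (6.11), RFX (5.57), CTCF (3.86), NFY (2.34), CACGTG E-boxes (2.27), NFI (1.70) and ZIC (1.46), and 14 were less frequent than in flanks. The exact sign test gave an adjusted p of 1.09e-53 at NRF1 and 0.0245 at NFI, whose ratio over replicates was 1.19 ± 0.00221 (SD, n = 2), below the minimum of 1.2; the NFI call was kept in 1 of 9 other settings. Against shuffled summit windows, distal MEIS, ZIC and EBF sites were no longer called, distal NFY fell to 0.946, and promoter NFI and ZIC to 0.50 and 0.920. Of the 14 less frequent at promoters, 8 had ratios above 1 against that background: POU (3.38), MEF2 (2.0), TATA box (1.86), TAATTA (1.62), SOX (1.39), TEAD (1.15), and HOX-PBX (1.31) and ROR (1.04), the last 2 without passing (exact sign test, unadjusted p = 0.0584 and 0.840). In replicate 1 alone, with 6739 distal summits, the distal ratios were 68 for RFX, 12 for NRF1, 8.0 for CREB, 4.71 for SP/KLF, 3.48 for ETS and 2.26 for NFY, and the promoter ratios 33.7 for NRF1 and 14.2 for YY1. The distal flank share in the series list was 0.0326% for RFX and 0.0217% for NRF1, so their ratios rest on few flank matches.

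**Figure D5:**
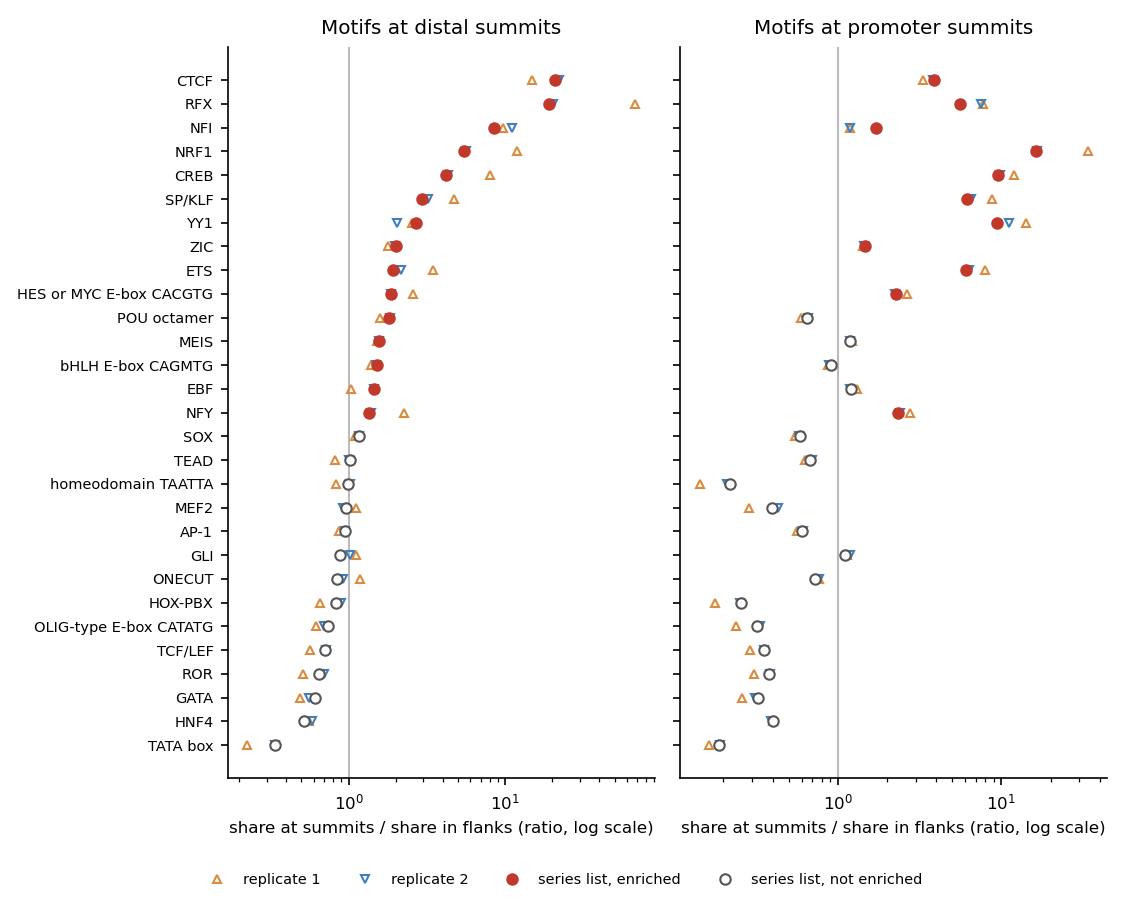
Ratio of the share of summits with a motif to the share of flank windows (log scale) at distal and promoter summits, in the series list (circles, red where enriched) and in each replicate (triangles). In the series list CTCF, RFX and NFI lead at distal summits with 20.8, 19 and 8.48, and NRF1 leads at promoters with 16.3. In replicate 1 RFX leads at distal summits with 68, against 14.9 for CTCF.

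The replicates were compared to ask how far the same chromatin was open in separate pools of embryos. Nearly all of the shorter list lay in the longer one: 97.9% of the summits of replicate 1 overlapped a peak of replicate 2, against 1.71% of randomly placed peaks (permutation p = 0.001, one-sided, the smallest that 1000 placements can give). In the other direction 64.6% of replicate 2 lay in replicate 1, against 1.04% at random. With replicate 2 reduced to its 31983 strongest summits, the shares were 97.6% and 72.8%. Fold enrichment agreed in rank across the 31322 paired summits (Spearman's rho 0.737, Pearson's r 0.742 on log2), which are not independent of each other.

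Promoter peaks were found again more often than distal peaks. Of the promoter peaks of replicate 1, 99.1% lay in replicate 2, against 92.6% of its distal peaks. This is a difference of 6.48 points (Fisher's exact test over peaks, two-sided, p = 9.66e-151). Overlap was decided by region, so summits of the same region share an outcome and are not independent in this test. With 1 summit per region the difference was 8.36 points (Fisher's exact p = 9.50e-88). It was 10.9 points when a set share of each region had to overlap, and 11.8 in the pseudoreplicated lists. The main difference held the same direction in each of 4 enrichment classes of like size. It was 5.20, 7.07, 8.65 and 0.380 points from the weakest class to the strongest. These classes do not equalise −log10 p or region length. In replicate 1, promoter and distal summits had a median enrichment of 5.23 and 5.30. Their median −log10 p was 23.6 and 19.5, and their median region length 1052 and 791 bp. Of the peaks of replicate 2, replicate 1 held 82.8% at promoters and 32.7% elsewhere. Of the 19271 it did not hold, 79.7% lay in the longer pseudoreplicated list of replicate 1.

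Chromosome X carried fewer peaks than autosomes. Its density was 0.505 ± 0.0222 (SD, n = 2) of the median autosome, with 11.5 summits per Mb in the series list against 24.4. Chromosome Y held 26 summits, and the embryos of both sexes were pooled. No test was made, and the ratio was 0.391 in the longer pseudoreplicated lists.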

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

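The tests of list length, of overall depth, of mitochondrial sequence and of the reproducibility threshold at Hox and forebrain genes were chosen after the result was seen. The deposited pooled ranked list holds peaks past its reproducibility threshold outside the list that the comparisons used: 121 on unplaced or unlocalized contigs, in 55 regions on 16 sequences with a median enrichment of 2.55, and 173 on main chromosomes, in 76 regions. The strongest of the latter reached 47.8 fold at chromosome 9, 24541943 to 24542233, and the place with most of them, chromosome 11 at 3160971 to 3199861, held 21 and overlaps the gene Sfi1, taken up below. With no control samples, these were noted because the count is above 0. The thresholded lists were made with 1 further parent file whose content is not stated, and no explanation was tested.

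Replicate 1 had the larger promoter share, 82.6% against 63.7%. List length alone is argued against, since the strongest summits of replicate 2 at replicate 1's length reached 68.8%. The reproducibility filter by IDR is argued against as the whole cause. In the pseudoreplicated lists, which are not thresholded on IDR, replicate 1 had 56.8% and replicate 2 had 50.6% at equal length. The gap was 13.8 points with the threshold and 6.29 without, but at unlike lengths of 31983 and 61091 summits. Those lists may also carry a reproducibility filter of their own. The 2 gaps thus give no size for the filter's part, which stays open. A lower depth of replicate 1 cannot be told apart from other explanations: −log10 p fell alike at distal and promoter sites (ratio of medians 1.00, interval 0.992 to 1.01, at passing summits, and 1.08 over all entries), the remaining gap may or may not arise at lower depth, and the reads that would decide were not analysed. Signal over background and a difference between the embryo pools stay open too, and no biological explanation was tested.

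The strongest distal peaks reached 55.4 fold. Matches to the mitochondrial genome covered 4 of their 9 regions against 7 of 13295 other distal regions (Fisher's exact p = 3.18e-11), so for these 4 reads of mitochondrial origin may be placed there, a candidate explanation. Of the 5 counted as without such a match, of which 1 was 48.3% covered and so just under the minimum, 1 had another nuclear copy, against 3 of 100 random regions, and with 5 regions this stays undecided. At Sfi1, 16 of 17 regions had another copy in the assembly, in line with reads shared between copies. No biological explanation was tested.

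Promoters of Hox paralogs 6 to 13 and of forebrain genes lacked peaks although rich in CpG. The reproducibility threshold is argued against for the Hox genes, of which 3 of 24 gained a promoter peak in the looser pooled list (exact 95% interval 2.66% to 32.4%). For forebrain genes 11 of 17 did (38.3% to 85.8%), and the list was not called there (adjusted permutation p = 0.136), so a weak signal below the threshold cannot be told apart from a missing one. Repeat sequence made up a median of 12% of these promoters against 8.30% of promoters with a peak in the same CpG classes, which leaves a part for unplaced reads undecided. No biological explanation was tested.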

How the results depend on the processing

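Alternatives with 1 summit per region, with a −log10 q of at least 2 or with the paired −log10 p were chosen after seeing the data; the others were planned. Of 99 alternatives to a comparison's value, 79 were counted as the same, 17 moved and 3 ended the call, and the cause was not tested unless stated. A single value counted as the same if it kept direction and side of the threshold or stayed within the spread. A number of called lists or motifs did so if it stayed within a set ratio of the main number, whichever ones were called. Thus 10 and 18 lists with fewer promoter peaks counted as the same as 14. The rank agreement between replicates was 0.708 in pseudoreplicated lists, 0.748 on −log10 p, 0.875 with 1 summit per region, 0.754 with the q filter and 0.699 on paired −log10 p. The Hox difference of 46.7 points fell to 20 with summits of at least median enrichment, and ranged from 6.67 to 20 with 1 replicate left out, where fewer peaks were called. Lists with promoter peaks more often than matched lists numbered 0, but 4 against unmatched lists (pan-neuronal, neural progenitor, housekeeping and cell cycle), 1 at 2.5 kb (astroglial), 1 each in the conservative list and at or above median enrichment (pan-neuronal), and 1 to 2 with 1 replicate left out. Lists with fewer fell from 14 to 7 in the replicated list, which holds more peaks, and to 10 at 2.5 kb. They rose to 17 in the conservative list, 16 without replicate 1 and 18 without replicate 2. The calls for Hox 6 to 8, Hox 9 to 13, forebrain, germ cell and olfactory genes held in all 10 alternatives, excitatory and epidermis genes in 9, cranial motor and endothelial genes in 8, serotonergic, noradrenergic and midbrain genes in 7, neural crest genes in 5 and vomeronasal genes in 4. The looser pseudoreplicated list, not among these 10, called 5 of the 14, without forebrain genes. Lists with more distal peaks rose from 3 to 6 unmatched, 5 with every gene within 50 kb and 7 in the replicated list, and the same 3 were among them each time; the call for neural progenitor genes was lost without replicate 2, at 1.0 distal summits per gene. Of 80 alternatives for the 10 genes with the most distal summits, 56 moved the count and 24 did not. Distal motif ratios ranged from 13.7 to 68 for RFX and promoter NRF1 from 12.7 to 64.4, all past the threshold. The X ratio was 0.391 in pseudoreplicated lists and 0.471 with 1 summit per region.

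Directions reversed as follows. All midbrain promoters (100%) had a peak in the replicated list. Against shuffled windows, distal ratios were 1.06 for OLIG-type E-box, 0.946 for NFY and 2.09 for TATA box, and promoter ratios were 1.39 for SOX, 0.50 for NFI, 1.62 for TAATTA, 1.31 for HOX-PBX, 3.38 for POU, 0.920 for ZIC, 1.04 for ROR, 1.15 for TEAD, 2.0 for MEF2 and 1.86 for TATA box. The promoter POU ratio was 1.11 with 1 summit per region. Depth is unknown, so a missing peak is not shown to be closed chromatin, and the shorter list of replicate 1 limits each value without replicate 2.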

Other observations

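The tests of motif sites near lineage genes, at the end of this part, were chosen before their results were seen. The gene list test in the looser pooled list was not among the planned settings. The gene classes were described after the data were seen. No test was made against protein-coding genes, of which 56.1% had a promoter peak. A peak lay within 1 kb of a start of 735 of 5854 long intergenic RNA genes (12.6%; 9.65% ± 2.39 over replicates, SD, n = 2), of 805 of 2959 antisense RNA genes (27.2%) and of 339 of 790 processed transcripts (42.9%). With starts near a protein-coding start left out, the shares were 8.33%, 10.2% and 22.0%. Processed pseudogenes, copies made by reverse transcription, had a peak at 128 of 9940 (1.29%) and microRNA genes at 214 of 2202 (9.72%). These shares were 1.15% and 3.88% with starts near a protein-coding start left out.

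In the looser pooled list, the rhombic lip and granule cell genes, which make cerebellar granule neurons and other dorsal hindbrain neurons, had a promoter peak at all 21 members against 17.5 in matched lists (adjusted permutation p = 0.00550). In the main list 13 of the 21 had one, fewer than the 15.8 in matched lists (adjusted permutation p = 0.207), so the direction was opposite. The adjusted permutation p of the rhombic lip and granule cell lineage over the other settings ranged from 0.111 to 1.0. The looser list called 5 lists with fewer promoter peaks where the main list called 14, and forebrain (adjusted permutation p = 0.136), endothelial (0.348) and epidermis genes (0.403) were among those not called. In the looser list Hox paralogs 1 to 5 had a promoter peak at 12 of 15, paralogs 6 to 8 at 1 of 8 (Hoxb7) and paralogs 9 to 13 at 2 of 16 (Hoxc13 and Hoxd9), which were picked out after their values were seen. The 11 distal regions that matched the mitochondrial genome had a median enrichment of 21.8 against 5.24 at other distal regions, and all 11 were found in both replicates.

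It was asked whether sites of lineage factors are more frequent near the genes of their lineage, as a hypothesis. SOX sites marked 14.5% of distal summits near progenitor genes and 13.1% of the others (Fisher's exact p = 0.563). CAGMTG E-boxes marked 27.6% near pan-neuronal genes and 26.9% elsewhere (Fisher's exact p = 0.856), and ZIC sites marked 8.77% near rhombic lip genes and 8.56% elsewhere (Fisher's exact p = 0.867). All tests were two-sided, and none found a difference, which does not show that there is none.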
